A study of Caenorhabditis elegans with 14 samples.

How the data were processed

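Total RNA of wild-type C. elegans was hybridised to 14 Affymetrix arrays, 5 sham, 5 microwave, 2 heat control and 2 heat shock, grouped by their labels. The values analysed were linear ratios as deposited by the authors. Per the labels' protocols the array images were read in GCOS and normalised with MAS 5, and the submitters' processing notes name RMA without a version; which of them made the values was not given in the sources used here, nor was a genome build. That the 5 sham columns hold only 1 (0 values differ), and that the 2 heat control columns sum to 2 within 0.001 for every probe set, was found from the values. The baseline of each microwave and heat shock column was not stated and was inferred. Per the labels, worms of 1 culture were divided between the microwave and the sham plates, and RNA of 3 exposure runs was pooled per array; the p-values measure the spread between such pools. The heat arrays carry the microwave protocol text, so their exposure is not described here. The array information sheets held no scan date, so no batch could be tested.

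Analysis used R 4.3.3 and limma 3.58.1 on log2 ratios of the 22548 probe sets left after 77 control probe sets were removed. The design fixed before the data were examined assumed intensities, with a floor and a comparison of 2 groups. Because the deposited values were ratios, no floor was set, and the microwave test became a fit of the mean of the 5 log2 pair ratios against 0, which holds the pairing. The spread of the sham arrays themselves enters only through the ratios. The heat test compared 2 arrays with 2, without a block. The difference between effects was fitted over the 9 arrays with measured spread. Variances were moderated with eBayes (prior degrees of freedom 3.44 for microwave and 3.32 for heat), p-values were two-sided and adjusted by Benjamini-Hochberg, and the threshold was 0.05. The replicate numbers of the heat arrays were not taken to pair the samples.

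Probe sets were named through the platform annotation, with symbols looked up by gene identifier in the RefSeq gene table of assembly WBcel235, which was used for names and gene length. Of the tested probe sets 20766 had 1 gene, 887 had several and 895 were not listed; 17118 genes were measured, and 99.7% had a length. Gene values are the mean of a gene's single-gene probe sets, since ratios do not show which probe set is brightest. Genes were named by a rule set before the data were examined: adjusted p under 0.05 and no overlap between groups, the 12 largest increases and 12 largest decreases chosen on the probe set with the smallest p, or, where fewer than 6 genes passed, the 10 with the smallest unadjusted p, together with 24 fixed stress and yolk genes, of which 18 had a single-gene probe set, and up to 4 examples per list. In the microwave comparison 0 genes met the first part. The 32 gene lists came from background knowledge and were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry.

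The fits were tested on simulated data with 200 changed probe sets of 22548, 50 at each fold. For microwave, with variances from the fitted prior, 38% of 1.25-fold, 76% of 1.5-fold and 98% of 2-fold changes were recovered, and 0 of 156 calls were false; with the moderated variances these shares were 28%, 86% and 100%, and 1 of 158 calls was false. For heat, with the fitted prior, 0% of 2-fold and 82% of 4-fold changes were recovered, and 6 of 47 calls were false; with the moderated variances 100% of 4-fold and 74% of 2-fold changes were recovered, and 22 of 114 calls were false. At probe set level false calls in the heat fit thus exceeded the nominal share. At gene level 1 of 34 calls was false with the fitted prior and 14 of 108 with the moderated variances. Each setting was simulated once. In both comparisons a proteasome list shifted by 1.5-fold was called with the preset correlation and 0 of the other lists were. The estimated correlation was not tried on simulated data. With 4 residual degrees of freedom for microwave and 2 for heat, that test has little power, so a list that fails it is not shown to be unchanged. The noise was drawn independently for each gene, so false list calls from correlation between genes could not arise there.

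Alternatives were quantile normalisation of the microwave ratios, median centring, removal of probe sets that can match several genes, other variance models, a replicate block in the heat fit, array weights, removal of a lowess trend on gene length, and leaving out each pair or array.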

Results

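Gene expression was measured in wild-type N2 nematodes (Caenorhabditis elegans) on 14 single-colour Affymetrix arrays with 22625 probe sets. Synchronised cultures kept at 15 °C were grown to the L4 larval stage, the last stage before adulthood. In 5 sham arrays and 5 microwave arrays, worms had spent 2.5 h at 26 °C in a transmission line cell without or with a continuous microwave field. The labels give an absorbed power of 5 to 40 mW per kg, and their protocols name the frequency as 1.8 GHz in 1 place and 1 GHz in another. RNA of 3 exposure runs was pooled for each array. A further 2 arrays were labelled heat control and 2 were labelled heat shock; the temperature and duration of that treatment were not given in the sources used here. The deposited values were linear ratios. All 5 sham columns held exactly 1 for every probe set, so each microwave column was read as a ratio to the sham array of the same number. The 2 heat control columns were ratios to their own mean, and the heat shock columns were read as ratios to the same mean. Absolute signal and signal over background were therefore unknown, and precision was limited by the number of arrays.

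The 5 microwave to sham pairs differed in spread. The standard deviation of the log2 ratios over probe sets was 0.387 in pair 1, and in the other 4 pairs it lay between 0.101 and 0.164. The log2 ratio of the 3' probe sets minus that of the 5' probe sets was averaged over 5 worm control transcripts. This mean was -0.74 in pair 1 and between -0.13 and 0.03 in the other 4. In pair 1 the transcripts differed, with catalase at -1.89, actin at -1.05, Gapdh at -0.62, ubiquitin at -0.19 and gly14 at 0.03. Over all 5 pairs the mean difference was -0.21 ± 0.30 (SD, n = 5). An exact two-sided sign-flip test gave p = 0.125, where 0.0625 is the smallest p that 5 pairs allow. Correlations across probe sets between pairs ranged from -0.37 (pairs 1 and 4) to 0.34 (pairs 3 and 5), and pairs 3 and 4 correlated at -0.31; probe sets are not independent replicates. Each microwave ratio was read in the direction set by the sham column of 1.

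**Figure D1:**
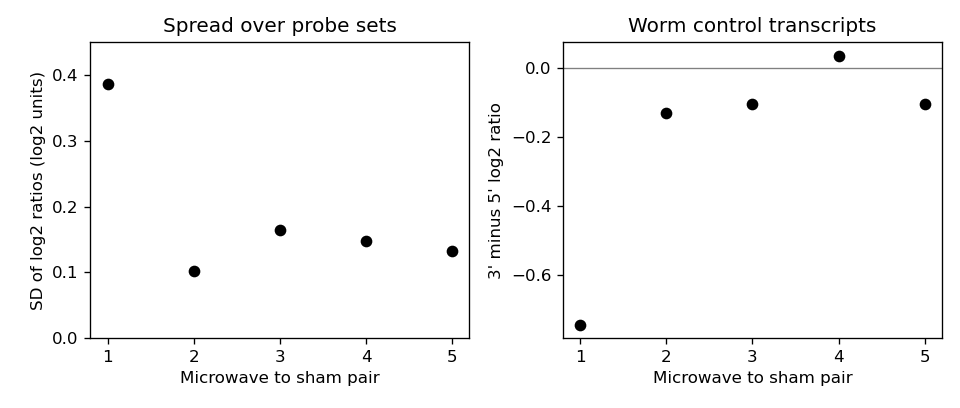
Left, standard deviation of the log2 ratios over 22548 probe sets in each of the 5 microwave to sham pairs; right, mean log2 ratio of the 3' minus the 5' probe sets of 5 worm control transcripts in each pair. Pair 1 lies at 0.387 and -0.74, outside the range of the other 4 pairs in both.

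The first comparison asked whether the microwave field altered transcript levels in worms held at a matched temperature. No probe set of the 22548 tested passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), and the lowest adjusted p was 0.861. At an unadjusted p under 0.05 there were 782 probe sets, 460 higher and 322 lower, where 1127 were expected by chance. That unadjusted count was 505 without pair 2, 424 without pair 3, 1748 without pair 4 and 390 without pair 5, 1217 after quantile normalisation and 1432 with array weights, and 0 probe sets passed by limma in each. At the level of 17118 genes, 0 passed by limma and 571 had an unadjusted p under 0.05. The 95% interval of the fold change lay within 1.5-fold of no change for 97.2% of probe sets, and within 2-fold for 99.8%. These shares cover all tested probe sets, since ratios do not show which transcripts were detected. The share among expressed genes is therefore unknown. Only 1 probe set had a mean ratio over 2-fold.

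Genes that respond to heat and to unfolded protein showed small ratios in the microwave comparison. The log2 fold change of hsp-70, which encodes a heat-inducible cytosolic Hsp70, was 0.14 ± 0.05 (SE, n = 5), and it was above 0 in 5 of 5 pairs (limma adjusted p = 0.872). The small heat shock protein genes hsp-16.2 and hsp-16.41 had log2 fold changes of -0.18 ± 0.16 and -0.09 ± 0.11, each above 0 in 2 of 5 pairs. The constitutive Hsp70 gene hsp-1 stood at 0.20 ± 0.09, the Hsp90 gene hsp-90 at 0.07 ± 0.07 and hsp-110 at 0.23 ± 0.08. In the endoplasmic reticulum, the BiP genes hsp-3 and hsp-4 stood at 0.31 ± 0.11 and 0.12 ± 0.09. The mitochondrial chaperone genes hsp-6 and hsp-60 stood at 0.11 ± 0.07 and 0.40 ± 0.16; the highest hsp-60 log2 ratio of a pair was 1.15, in pair 1. The small heat shock protein hsp-12.6 stood at -0.08 ± 0.05. Values for the glutathione transferase gst-4 were -0.003 ± 0.13, for the superoxide dismutase sod-3 -0.04 ± 0.08, for the metallothioneins mtl-1 and mtl-2 -0.16 ± 0.09 and -0.07 ± 0.09, and for the cadmium-responsive cdr-1 -0.04 ± 0.05. The yolk protein genes vit-2 and vit-6 stood at 0.12 ± 0.08 and 0.10 ± 0.06. Without pair 1, hsp-6 stood at 0.04, hsp-60 at 0.21, hsp-1 at 0.10, hsp-90 at -0.006, hsp-110 at 0.14, hsp-3 at 0.20, hsp-4 at 0.03, vit-2 at 0.04, vit-6 at 0.04, gst-4 at 0.13, hsp-16.2 at -0.09 and hsp-70 at 0.13. On the same basis mtl-1 stood at -0.09, mtl-2 at -0.007, cdr-1 at -0.007, hsp-12.6 at -0.05, hsp-16.41 at -0.06 and sod-3 at -0.04; without pair 3, hsp-16.41 stood at 0.008, sod-3 at 0.05 and mtl-2 at -0.02. Adjusted p-values of these genes over all 5 pairs were 0.872 or more.

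The 10 genes whose probe sets had the smallest unadjusted p were phkb-1, Y69A2AR.16, C27C7.1, ogdh-1, egl-30, hmg-20, chch-3, srh-89, pdi-2 and cogc-1. Averaged over each gene's probe sets, their log2 fold changes ran from 0.10 ± 0.06 for cogc-1 to 0.29 ± 0.06 for C27C7.1 (SE, n = 5), and without pair 1 from 0.06 to 0.25. In 9 of them the ratio was above 1 in 5 of 5 pairs, and in cogc-1 it was above 1 in 4. These genes were chosen for small p-values in the same pairs, so agreement in sign follows in part from that choice. Their limma adjusted p was 0.872. The mitochondrial genes ogdh-1, for a subunit of 2-oxoglutarate dehydrogenase, and chch-3 stood at 0.18 ± 0.06 and 0.23 ± 0.05. The disulphide isomerase gene pdi-2 stood at 0.11 ± 0.05.

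Of the 32 gene lists, 0 had a member past the adjusted threshold, over all genes or adjusted over the list alone. With camera's preset correlation of 0.01, 17 lists stood apart from the remaining genes, 12 toward higher and 5 toward lower ratios. With a correlation estimated from the data 0 lists passed (lowest adjusted p = 0.604 with an estimated correlation), fry, which tests a list on its own, called 0 (lowest adjusted p = 0.728), and with the preset correlation 5 lists passed without pair 1 and 11 passed without probe sets that can match several genes. The exact sign-flip test on list means gave p = 0.0625 or more, the smallest that 5 pairs allow.

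List shifts in the microwave comparison were 0.17 or less on the log2 scale. The proteasome list had a mean log2 fold change of 0.13 over 33 genes, with 32 above 0 and examples rpn-1 at 0.29 ± 0.11 and pas-7 at 0.31 ± 0.17; its mean was 0.60 in pair 1 and between -0.04 and 0.08 in the other 4 (camera adjusted p = 1.41e-06; adjusted p = 0.604 with an estimated correlation). Germ line genes averaged 0.13 (cye-1 at 0.34 ± 0.14, gld-1 at 0.30 ± 0.12), oocyte and eggshell genes 0.12 (puf-3 at 0.30 ± 0.17), reference genes 0.15, and vitellogenins 0.17, of which vit-4 stood at 0.46 ± 0.22. Body wall muscle genes averaged 0.10 (unc-54 at 0.24 ± 0.14), cytosolic chaperones 0.09 (cdc-37 at 0.29 ± 0.12), the endoplasmic reticulum unfolded protein list 0.09, the mitochondrial unfolded protein list 0.09, intestine 0.09 (act-5 at 0.25 ± 0.08), fatty acid metabolism 0.08 (pod-2 at 0.36 ± 0.18) and the respiratory chain 0.06 (atp-1 at 0.28 ± 0.11). The lists toward lower ratios were antimicrobial peptides and lysozymes at -0.07 (nlp-29 at -0.27 ± 0.15), major sperm proteins at -0.04, collagens at -0.04 (col-50 at -0.24 ± 0.08), cytochrome P450 enzymes at -0.03 (cyp-14A3 at -0.22 ± 0.08) and C-type lectins at -0.03. In pair 1, which had the lowest 3' minus 5' difference, the endoplasmic reticulum list averaged 0.41, the mitochondrial list 0.36, intestine 0.33, germ line genes 0.48, oocyte and eggshell genes 0.60, reference genes 0.52, vitellogenins 0.48, chaperones 0.39, fatty acid metabolism 0.42, antimicrobial genes -0.29 and major sperm proteins -0.28. Each of these 17 lists lost its call with an estimated correlation, at adjusted p-values from 0.604 to 0.756 with an estimated correlation. Without pair 1, body wall muscle, vitellogenins, reference genes, germ line and cytochrome P450 enzymes passed the preset test, with means of 0.07, 0.09, 0.06, 0.05 and -0.03. In the other 4 pairs the proteasome averaged 0.01, chaperones 0.02, the endoplasmic reticulum list 0.01, the mitochondrial list 0.02, intestine 0.03, oocyte and eggshell genes 0.005, the respiratory chain 0.02, antimicrobial genes -0.02, collagens -0.01 and C-type lectins -0.01. The genes given as examples were nearer 0 without pair 1: rpn-1 stood at 0.16, pas-7 at 0.09, cye-1 at 0.17, gld-1 at 0.16, puf-3 at 0.07, vit-4 at 0.17 and unc-54 at 0.13. On the same basis cdc-37 stood at 0.15, act-5 at 0.18, pod-2 at 0.13, atp-1 at 0.15, nlp-29 at -0.10, col-50 at -0.17 and cyp-14A3 at -0.14. Fatty acid metabolism, at -0.01, and major sperm proteins, at 0.01, had the opposite sign without pair 1.

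The other 15 lists did not pass either test. The small heat shock protein list averaged -0.04 over 12 genes (camera adjusted p = 0.417), and the exact sign-flip test of its list mean gave p = 0.625. UDP-glucuronosyltransferases averaged -0.02, metal response genes -0.05, the intracellular pathogen response -0.02, DNA damage response 0.05, other sperm genes -0.02, embryo -0.02, moulting 0.03, histones -0.01, DAF-16 induced genes -0.01, pharynx 0.01, neurons -0.01, hypodermis and seam 0.004, ribosomal proteins -0.003 and oxidative stress defence -0.001. Without pair 1 the small heat shock protein list averaged -0.01, metal response genes -0.01, DNA damage response -0.01, other sperm genes 0.01, embryo -0.0003, histones -0.01, DAF-16 induced genes -0.03, pharynx 0.06, neurons -0.02, hypodermis and seam 0.002, ribosomal proteins -0.02 and oxidative stress defence -0.01. The mean and the median differed in sign for pharynx and for hypodermis and seam, and the mean and the camera direction for oxidative stress defence.

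The second comparison set the arrays labelled heat shock against those labelled heat control, as a treatment known to change expression. In the arrays labelled heat shock the heat-inducible chaperone genes were lower, opposite to the known response of these genes to heat. The small heat shock protein genes hsp-16.41 and hsp-16.2 had log2 fold changes of -4.98 ± 0.36, which is 31.6-fold lower, and -4.86 ± 0.17 (SE, n = 2 per group; limma adjusted p = 0.00248 and 0.00232). The cytosolic hsp-70 was 10.1-fold lower, at -3.34 ± 0.17. The 4 probe sets that match 2 chaperone genes each, so that no gene can be named, ran from -4.07 to -5.34. Every direction below is that of the labels, and it turns throughout if the labels or the ratio ran the other way.

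**Figure D2:**
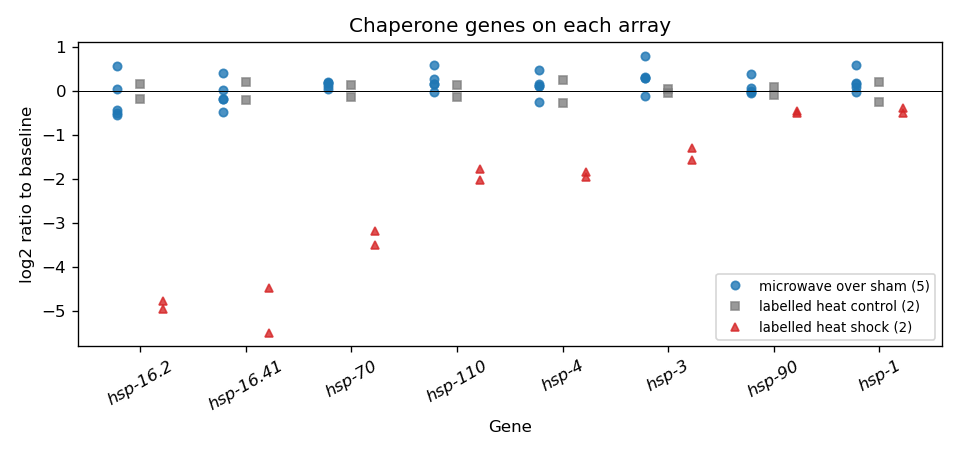
Log2 ratio of 8 chaperone genes on each array: 5 microwave arrays over their sham arrays, 2 arrays labelled heat control and 2 labelled heat shock, the latter 4 over the heat control mean. In the arrays labelled heat shock hsp-16.2, hsp-16.41 and hsp-70 lie below -3, and in the microwave pairs these genes lie between -0.54 and 0.56.

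Past an adjusted p of 0.05 (limma) were 6774 of 22548 probe sets, 3317 higher and 3457 lower in the arrays labelled heat shock. At gene level 5129 of 17118 passed, 2600 higher and 2529 lower. The arrays labelled heat shock had medians 0.10 log2 units above those of the controls. With each array centred on its median 2177 probe sets were higher and 3943 lower. Of the 4224 genes called under both scalings, 4224 had the same direction. That was nearly certain beforehand, since centring shifts the log2 fold changes of all genes alike. Without replicate 1 of the arrays labelled heat shock 0 probe sets passed (lowest adjusted p = 0.0546, with 6642 at an unadjusted p under 0.05), and without replicate 2 there were 1108, with 7088 at an unadjusted p under 0.05, where the remaining array is assumed to vary like the controls. Without probe sets that can match several genes, 4338 passed. Simulated data of this size had 200 changed probe sets. There 12.8% or 19.3% of the calls were false, with variances from the fitted prior or with the moderated variances. In the same runs 82% or 100% of 4-fold changes were recovered. The false share depends on how many probe sets change, so it does not carry over to the 6774 calls.

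Of 18 measured cytosolic Hsp70 and Hsp90 chaperones and partners, 13 fell, 0 rose and 5 did not pass, with 13 adjusted over the list alone. Besides hsp-70, hsp-110 fell, at -1.89 ± 0.16, as did the p23 co-chaperone gene daf-41 at -1.92 ± 0.19, and hsp-90 passed at -0.47 ± 0.13 (limma adjusted p = 0.0475); hsp-1 stood at -0.43 ± 0.19 (adjusted p = 0.137). The camera adjusted p of the list was 4.98e-07 (adjusted p = 0.503 with an estimated correlation). With 2 residual degrees of freedom, 0 of the 32 lists passed with an estimated correlation, so those values say little about single lists. Of 19 genes of the endoplasmic reticulum unfolded protein response 11 fell and 8 did not pass, with 14 adjusted over the list alone (camera adjusted p = 1.84e-07; adjusted p = 0.503 with an estimated correlation). In that list xbp-1, for the transcription factor of the response, fell, at -1.97 ± 0.11, as did the degradation factor cup-2 at -2.09 ± 0.15 and the BiP genes hsp-3 and hsp-4 at -1.43 ± 0.15 and -1.87 ± 0.20. Of 12 small heat shock protein genes 4 fell, 2 rose and 6 did not pass, with 6 past adjusted over the list alone, and the list mean was -0.90 (camera adjusted p = 0.0375; adjusted p = 0.65 with an estimated correlation). The risers were hsp-12.1 at 1.08 ± 0.17 and hsp-12.2 at 0.52 ± 0.14; hsp-12.6 stood at -0.15 ± 0.13. With each array centred on its median 1 member rose and the list did not pass (camera adjusted p = 0.0535). In the mitochondrial unfolded protein list 3 of 13 rose and 3 fell, with 7 past adjusted over the list alone. There timm-23 rose, at 1.78 ± 0.20, as did ubl-5 at 1.37 ± 0.14, atfs-1 fell, at -0.97 ± 0.13, and hsp-6 and hsp-60 stood at 0.16 ± 0.17 and -0.04 ± 0.19.

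More genes rose than fell in both sperm lists. Of 23 major sperm protein genes, which encode the cytoskeletal protein of nematode sperm, 22 rose and 1 did not pass, with 22 past adjusted over the list alone, msp-142 at 2.38 ± 0.34 and msp-63 at 2.12 ± 0.22 (camera adjusted p = 4.88e-07; adjusted p = 0.624 with an estimated correlation). With each array centred on its median 19 of these genes rose. With the gene length trend removed, a step chosen after seeing the data, 12 rose and 0 fell, with a median log2 fold change of 0.76 against 1.10 as deposited (camera adjusted p = 7.52e-05); their median gene length was 384 bp. In msp-32 the 2 probe sets went in opposite directions, and the lower, at -1.68, was the 1 not marked as able to match several genes. The genes msp-50, msp-53 and msp-63 had only probe sets that can match several genes. The 22 rises may therefore in part repeat 1 signal. Over all lists, with the preset correlation, 2 passed toward higher values without such probe sets, against 4 with them. Of 41 other sperm genes 12 rose, 3 fell and 26 did not pass, with 16 past adjusted over the list alone, ssp-31 at 2.95 ± 0.18, ssp-33 at 2.86 ± 0.12 and spe-11 at -1.20 ± 0.17 (camera adjusted p = 0.0329; adjusted p = 0.503 with an estimated correlation). In the embryo list 9 of 42 rose and 1 fell, with 10 past adjusted over the list alone (camera adjusted p = 0.0177; adjusted p = 0.503 with an estimated correlation). With the gene length trend removed that list did not pass (camera adjusted p = 0.0695). Of 22 oocyte and eggshell genes and 5 vitellogenins 0 passed by limma, also adjusted over the list alone, and the 2 heat control arrays lay far apart in both lists: list means were -0.80 and 0.49 for oocyte and eggshell genes and -1.66 and 0.74 for vitellogenins. Among 15 germ line genes 1 rose (glp-1 at 0.56 ± 0.12) and 3 fell (him-3 at -1.18 ± 0.15), with 3 past adjusted over the list alone.

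More genes fell than rose in the lists of the proteasome, fatty acid metabolism, UDP-glucuronosyltransferases and DAF-16 induced genes. Of 33 proteasome genes 18 fell and 7 rose, with 26 past adjusted over the list alone, rpn-8 at -2.41 ± 0.12 and rpt-4 at -1.62 ± 0.13 against the core subunits pas-5 at 1.06 ± 0.14 and pbs-2 at 1.00 ± 0.12 (camera adjusted p = 0.000212; adjusted p = 0.503 with an estimated correlation). Of 22 fatty acid metabolism genes 7 fell and 2 rose, with 9 past adjusted over the list alone, including the desaturase genes fat-3 at -2.92 ± 0.32 and fat-2 at -2.47 ± 0.20 (camera adjusted p = 0.00125; adjusted p = 0.503 with an estimated correlation). UDP-glucuronosyltransferases, conjugating enzymes of detoxification, fell in 17 of 64 and rose in 4, with 23 past adjusted over the list alone, 21 lower and 1 higher with median centring, and ugt-44 at -2.43 ± 0.36 (camera adjusted p = 0.00125; adjusted p = 0.503 with an estimated correlation). Of 11 DAF-16 induced genes, 6 of which are in another list, 5 fell, with 5 adjusted over the list alone, among them icl-1 at -1.95 ± 0.17 and the catalase gene ctl-2 at -1.53 ± 0.13 (camera adjusted p = 0.00843; adjusted p = 0.503 with an estimated correlation).

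More genes fell than rose in the moulting, intestine, body wall muscle and reference lists. Of 18 moulting genes 5 fell and 0 rose, with 8 past adjusted over the list alone and 8 lower with median centring, lpr-3 at -2.78 ± 0.26 and noah-2 at -2.65 ± 0.35 (camera adjusted p = 0.000215; adjusted p = 0.503 with an estimated correlation). Of 12 intestinal genes 8 fell, with 9 adjusted over the list alone, the acid phosphatase gene pho-1 at -2.87 ± 0.29 and the esterase gene ges-1 at -1.25 ± 0.14 (camera adjusted p = 0.000311; adjusted p = 0.503 with an estimated correlation). Of 14 body wall muscle genes 10 fell and 1 rose, with 12 past adjusted over the list alone, unc-112 at -2.02 ± 0.20 and the tropomyosin gene lev-11 at 0.53 ± 0.12 (camera adjusted p = 0.000202; adjusted p = 0.503 with an estimated correlation). Of 8 reference genes 5 fell and 2 rose, with 8 past adjusted over the list alone, cdc-42 at -1.56 ± 0.13 and ama-1 at 0.78 ± 0.12 (camera adjusted p = 0.0304; adjusted p = 0.503 with an estimated correlation), and with median centring the list did not pass (camera adjusted p = 0.0535). C-type lectins rose in 53 of 220 and fell in 12, with 67 past adjusted over the list alone, clec-85 at 2.69 ± 0.16 and clec-174 at -3.45 ± 0.77 (camera adjusted p = 0.00174; adjusted p = 0.503 with an estimated correlation). With each array centred on its median 27 of these lectins rose and 16 fell, and 0 body wall muscle genes rose. Tissue, germ line and embryo lists were included as markers that a shift in stage or sampling could move. A difference in developmental stage between the arrays labelled heat shock and heat control was not tested, and it cannot be told apart here from the treatment.

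The remaining lists did not pass as a whole in the heat comparison. Of 24 oxidative stress genes 5 rose and 7 fell, with 13 past adjusted over the list alone, trx-2 at 1.33 ± 0.13 and the glutathione synthesis gene gcs-1 at -1.97 ± 0.17; gst-4 and sod-3 stood at 0.75 ± 0.52 and 0.13 ± 0.16. Of 7 metal response genes 1 rose, mtl-2 at 3.12 ± 0.51 (8.71-fold), and 1 fell, cdr-4 at -1.87 ± 0.44, with 4 past adjusted over the list alone; mtl-1 and cdr-1 stood at -0.26 ± 0.14 and -0.15 ± 0.13. Collagens rose in 36 of 145 and fell in 8, with 44 past adjusted over the list alone. Antimicrobial genes rose in 9 of 58 and fell in 9, with 23 past adjusted over the list alone, cnc-8 at 2.36 ± 0.19 and lys-10 at -3.86 ± 0.17. In the respiratory chain 7 of 38 rose and 10 fell, with 21 past adjusted over the list alone, the copper chaperone gene cox-17 at 2.20 ± 0.13 and nuo-4 at -2.31 ± 0.12. Cytochrome P450 enzymes rose in 5 of 73 and fell in 12, neurons rose in 3 of 21 and fell in 2, pharynx rose in 6 of 15 and fell in 1, and hypodermis and seam rose in 4 of 26 and fell in 6; adjusted over the list alone, 10, 5, 7 and 12 genes of these lists passed. With each array centred on its median cytochrome P450 enzymes rose in 2 and fell in 13, pharynx rose in 2 and fell in 1, and hypodermis and seam rose in 1 and fell in 7, and collagens rose in 26 and fell in 10. With the gene length trend removed cytochrome P450 enzymes rose in 10 and fell in 9, and antimicrobial genes rose in 6 and fell in 12. Ribosomal protein genes rose in 7 of 75 and fell in 1, histones rose in 5 of 26 and fell in 0, DNA damage response genes rose in 1 of 15 and fell in 2, and the intracellular pathogen response rose in 1 of 27 and fell in 2; adjusted over the list alone, 2, 5, 3 and 1 genes of these lists passed. With the gene length trend removed, the ribosomal protein list passed the preset test toward lower values (camera adjusted p = 0.0195). There 2 genes rose and 5 fell, with a median log2 fold change of -0.11 against 0.11 as deposited. With an estimated correlation the list as deposited did not pass (camera adjusted p = 0.97). That correlation was not estimated with the trend removed. The yolk genes vit-2 and vit-6 stood at -0.11 ± 0.73 and -0.23 ± 0.59. Without heat control replicate 1 both were lower, at -1.26 and -1.15, and without heat control replicate 2 both were higher, at 1.05 and 0.69. With 1 control array left, the spread between the controls did not enter these fits. By fry, 10 of the 32 lists passed (lowest adjusted p = 0.0295), all among those past camera with the preset correlation. They were cytosolic chaperones, the endoplasmic reticulum list, proteasome, C-type lectins and DAF-16 induced genes. Also past were other sperm genes, embryo, intestine, body wall muscle and reference genes. Major sperm proteins, small heat shock proteins, moulting, fatty acid metabolism and UDP-glucuronosyltransferases did not pass (fry adjusted p = 0.07 to 0.128). The mean and the median differed in sign for the mitochondrial unfolded protein, oxidative stress, cytochrome P450 and germ line lists. For antimicrobial genes, the intracellular pathogen response, vitellogenins and oocyte and eggshell genes both were above 0 while the camera direction was down; none of these lists passed.

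Genes were ranked for naming on the probe set with the smallest p, and the folds given here are means over a gene's probe sets, by which other genes, such as hsp-70 and mtl-2, exceed the last of those named. The increases named by this rule were nssp-36 (15.4-fold), the mitochondrial import gene timm-17B.2 (14.1-fold) and the collagen gene col-131 (12.9-fold), followed by W03C9.5, D2023.1, rnh-1.3, K08F11.1, the neuropeptide-like gene nlp-20, F08F3.8, mxl-1 and the RNA polymerase subunit gene rpb-12, at 10.1-fold to 7.87-fold, and F58D5.2 at 4.49-fold. Beside the 2 hsp-16 genes, the decreases named were F45D3.4 (23.6-fold), best-14 (15.3-fold), H40L08.2 (15.3-fold), lys-10 (14.5-fold), Y54B9A.1 (14.2-fold), T02H6.3, fbxa-72, R107.5 and spia-1 (12.5-fold to 10.9-fold) and ule-3 (5.50-fold). Limma adjusted p-values of these 24 genes ran from 0.00232 to 0.00983.

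The difference between both effects was then tested in a single model. The heat effect minus the microwave effect passed in 8371 of 22548 probe sets (limma), 4585 above 0 and 3786 below, and with the sign of the heat effect turned 6944 passed. Without heat shock replicate 1 there were 5402. Median centring gave 3064 above 0 and 4292 below. Across 17118 genes, which are not independent replicates, the log2 fold changes of the microwave and heat comparisons had a Pearson correlation of -0.30 and a Spearman correlation of -0.33. With the heat sign turned these values change sign. With single pairs the Pearson correlation was -0.41 for pair 1, -0.06 for pair 2, -0.01 for pair 3, 0.19 for pair 4 and -0.08 for pair 5, and it was 0.04 over the 4 pairs other than pair 1. Heat control and sham arrays were not compared, since each set was scaled to its own baseline.

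**Figure D3:**
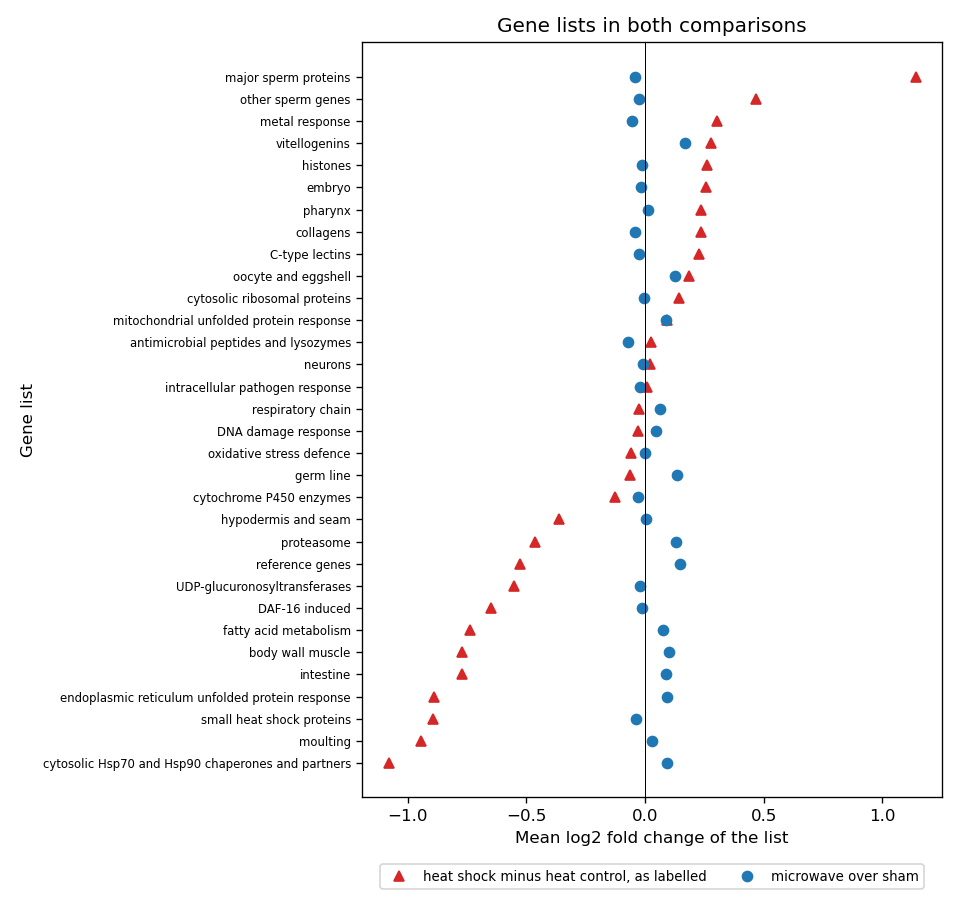
Mean log2 fold change of each of 32 gene lists in the microwave comparison (circles) and in the comparison of arrays labelled heat shock and heat control (triangles). Microwave means lie between -0.07 and 0.17, and heat means between -1.08 for cytosolic chaperones and 1.14 for major sperm proteins.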

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

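The tests of label direction and developmental stage were chosen after the result was seen; so was the use of array scaling, RNA integrity and correlation within lists as explanations, though median centring, the 3' to 5' measure and the estimated correlation had been planned. The gap of the most extreme pair from the nearest other was set against the range of the 5 microwave to sham pairs for 64 values, and 12 stood apart, 11 of them in pair 1, where chance marks about 1 in 20, or 3.2. The 64 values share the same 5 pairs and are not independent, so 1 deviating pair can set many of them apart together. In pair 1 the standard deviation of the log2 ratios was 0.387 and the 3' minus 5' difference -0.742. Mean log2 ratios of pair 1 that stood apart were 0.386 for cytosolic chaperones, 0.60 for the proteasome, 0.283 for DNA damage response, 0.42 for fatty acid metabolism, -0.157 for other sperm genes, 0.482 for germ line, 0.325 for intestine and 0.516 for reference genes. The log2 ratio of hsp-6 was 0.401 in pair 1, and the moulting list stood apart in pair 3 at 0.0951.

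The wide spread of pair 1 was weighed first. A trend on gene length is argued against as its whole source: with that trend removed, the standard deviation over genes in pair 1 was still 2.34 times the highest of the other pairs, against 2.31 times before. A difference in RNA integrity between the 2 arrays may contribute, since the 3' minus 5' difference of pair 1 was 5.69 times as large as the largest of the others. The hybridisation spike-in probe sets had a mean log2 ratio of -1.31 in pair 1, against -0.31 to 0.33 in the others. That value did not stand apart by the rule above, and what lies behind it was not tested. A difference in developmental stage between the 2 pools is also open, since 4 of 4 stage lists lay outside the central 95% of 10000 random lists in pair 1, with oocyte and eggshell genes at 0.60 and major sperm proteins at -0.28. The proteasome list moved as far, so the shift was not limited to stage genes, and an effect of the microwave field in that pair was not tested.

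The lower heat shock genes in the arrays labelled heat shock were weighed second. Scaling and gene length are argued against: the mean of hsp-16.2, hsp-16.41 and hsp-70 was -4.50 ± 0.22 (SE) with each array centred on its median and -4.53 ± 0.22 with the length trend removed, against -4.39 as deposited. A candidate explanation is that the labels or the direction of the ratio run opposite to the treatment. The median of the 17 other cytosolic chaperones was -1.06, at percentile 0 of 10000 random lists. A real decrease of chaperone genes under correct labels would give a low median too, so this value cannot tell the 2 apart. Random lists also leave out the correlation between chaperone genes. With an estimated correlation the list with hsp-70 included did not pass (camera adjusted p = 0.503). That test had 2 residual degrees of freedom and passed 0 of the 32 lists, so its failure carries little weight. By fry the same list passed (adjusted p = 0.0295). The 2 heat control columns sum to 2 within 0.001, as arrays over their mean do, which argues against an inverted ratio in those columns; the heat shock columns allow no such check, and a lasting decrease of these transcripts after heat was not tested.

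The number of gene lists called in the microwave comparison was weighed last. Turning the signs of pairs gives 16 patterns, too few for a share under 0.05: the real pattern called 17 lists, the highest other 18, and 3 patterns, the real one included, called at least as many. For probe sets at an unadjusted p under 0.05 the real pattern gave 782 and the highest other 2687, and 4 of the 16 patterns gave as many; that other pattern turns pair 4, and the several-fold higher count points to a structure of the pairs, where pair 4 correlated at -0.37, -0.31 and -0.24 with pairs 1, 3 and 5. The Spearman correlation of the pair ratios with gene length was 0.27, -0.02, 0.30, -0.32 and 0.18 in pairs 1 to 5. In that trend pair 4 also stood opposite to pairs 1, 3 and 5, and whether it accounts for the structure was not tested. As the source of the list calls gene length is argued against, since 18 lists were called with its trend removed. Pair 1 alone may account for most calls, since 5 lists were called without it. With an estimated correlation 0 lists were called. That test had 4 residual degrees of freedom and was not tried on simulated data. Its count therefore cannot show whether correlation between the genes of a list made the calls.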

How the results depend on the processing

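Array weights, robust eBayes, the gene length trend, the fit of 9 arrays and the turned heat sign were chosen after seeing the data. The microwave comparison gave 0 probe sets by limma under quantile normalisation, median centring, each left-out pair and the other alternatives that have a measured spread, with 390 to 1748 at an unadjusted p under 0.05 when a pair was left out. A microwave fit with no replicate block says nothing here, since the sham columns have no spread. The share of intervals within 1.5-fold was 94.1% to 99.96% without each pair. Microwave lists fell from 17 to 0 with an estimated correlation and to 11 without probe sets that can match several genes, and numbered 5 to 19 when a pair was left out. Heat lists fell from 15 to 0 with an estimated correlation and to 10 without probe sets that can match several genes. Of those 10, 2 were toward higher and 8 toward lower values, against 4 and 11 with all probe sets. For the heat comparison the count of 6774 probe sets became 4338 without probe sets that can match several genes, where fewer were tested, 4312 with the replicate block, and 0 to 6594 when an array was left out; the cause of the last 2 was not tested. The deviations of heat arrays with the same number correlated at -0.05, so the block rests on a shared number only, and it left the heat lists at 15. The difference between effects passed in 5402 to 9241 probe sets when an array was left out. When 1 array or pair was left out, the correlation across genes was -0.338 to 0.0379, and of these it was above 0 only without pair 1. The small heat shock protein mean was -0.0795 to 0.00803 in microwave and -1.11 to -0.68 in heat, and the 3' minus 5' difference -0.27 to -0.08. Over the 5 fits with a pair left out, named genes kept their sign in the microwave comparison in 681 cases and lost it in 59. Among the named genes of the heat comparison that changed sign when a heat control was left out were sip-1, vit-4, vit-2 and vit-6. With 1 control array left, the spread within groups came only from the 2 arrays labelled heat shock. Without heat control replicate 1 sip-1 stood at -0.695, vit-4 at -0.976, vit-2 at -1.26 and vit-6 at -1.15, and without replicate 2 at 1.69, 1.73, 1.05 and 0.685. The 2 heat control arrays differed by 5.22-fold in sip-1, 6.54-fold in vit-4 and 4.95-fold in vit-2, and lay at -1.19 and 0.643 in vit-6. The sign of these genes thus depended on which control was kept. Why the controls differed was not tested. Over the 4 fits with 1 heat array left out, named genes lost a call in 193 cases and gained one in the same direction in 23. Not run, because ratios hold no level, were the filter on dim probe sets, the variance trend, the floor and pseudocount and the brightest probe set; no scan batch was given, quantile normalisation of the heat arrays would give the heat control ratios the width of the effect, and heat control and sham share no baseline. Signal over background was unknown.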

Other observations

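The families below were grouped by symbol prefix after the data were seen. In the arrays labelled heat shock, 15 of 18 vacuolar ATPase genes (vha) fell, with a median log2 fold change of -1.16, as did 17 of 29 DnaJ genes (dnj) with 1 rising, and 7 of 11 peroxisome genes (prx) with 0 rising. More neuropeptide genes rose than fell: 13 of 25 flp genes rose and 0 fell, and 30 of 58 nlp genes rose and 5 fell. Of 43 nssp genes 27 rose and 1 fell. The median gene lengths of the nssp, nlp and flp families were 936, 831 and 1424 bp, and the median heat log2 fold change was 0.28 over the 3417 shortest genes and 0.095 over the 3414 longest. With the gene length trend removed, a step chosen after seeing the data, 21 nssp genes rose and 1 fell, 25 nlp genes rose and 8 fell, 14 flp genes rose and 1 fell, and 16 vha, 17 dnj and 7 prx genes fell. Of 165 families with 10 or more genes 52 passed camera with the preset correlation, 57 with that correlation and the gene length trend removed, and 0 with an estimated correlation.

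The 2 heat control arrays differed by more than 2-fold in 474 of 17118 genes, where the 2 heat shock arrays did so in 33. The largest differences were in far-3 (60.5-fold), gst-21 (49.6-fold) and irg-5 (20.3-fold), lower in replicate 2, and in cyp-37B1 (log2 difference of 3.44) and dod-3 (10.6-fold), higher in replicate 2. The yolk genes vit-5, vit-4, vit-1 and vit-2 were 6.97-fold, 6.54-fold, 5.21-fold and 4.95-fold higher in replicate 2. These genes were chosen after their values were seen.

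In pair 1 of the microwave comparison, 1 of the probe sets of vit-4 had a log2 ratio of 4.53, against 0.23 to 0.63 in the other 4 pairs, and the hybridisation spike-in probe sets had a mean log2 ratio of -1.31, against -0.31 to 0.33 in the other 4.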
